A study of Drosophila melanogaster with 3 samples.

How the data were processed

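Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected 0 to 24 hours after egg laying, from a transgenic line that expresses the product of the gene CG17361 fused to green fluorescent protein (GFP). Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and the fusion protein was precipitated with an antibody against GFP. The 3 libraries are labelled as biological replicates of 1 group, so no comparison between groups was possible. Whether they came from separate collections of embryos is not stated in the labels.

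The deposited files used here are 14 peak lists, and the reads were not analysed. Per the file listings that accompany the samples, the authors mapped the reads to the dm6 assembly and made each peak list against a control library, whose own values were not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. For each replicate the authors deposited a ranked list and a thresholded list, and for the series 4 ranked and 4 thresholded lists made from all replicates' alignments, 1 of them named conservative. The thresholded lists were filtered by the irreproducible discovery rate (IDR), which compares the ranks of peaks in a pair of lists, and the ranked lists also hold peaks that do not pass it. Per the layout of the ranked files, the authors' global IDR is deposited as a −log10 value, and every line of every thresholded list had a value of at least 2, an IDR of 0.01 or less. The peak signal is a score deposited by the authors, on a scale not given in the sources used here. It was used only to rank, filter and describe peaks within a list. No read counts accompany the lists, so the depth behind each replicate is unknown and peak numbers of replicates may differ through depth alone.

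The replicates behind each series-level list are not named in the sources used here. They were identified by comparing the 2 input lists recorded in each series-level ranked file with the 3 replicates' ranked lists, line by line. In 3 of the 4 files, between 63.3% and 94.1% of the lines on each side carried an interval and signal identical to those of exactly 1 replicate, and none were identical to the others. These lists therefore compare replicates 1 and 2, replicates 1 and 3, and replicates 2 and 3. The remaining file matched no replicate and is called the pooled set. The conservative list was the list of replicates 1 and 3 and was used as the main peak set. All series-level lists draw their intervals and signals from a shared peak list made from all 3 replicates' alignments. They differ in the replicates whose ranks IDR compared. A setting without a replicate used the list that compares the remaining replicates, so the alignments of the replicate left out still contributed to its peaks.

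Many intervals were deposited on several lines with different summits. A peak was therefore an interval counted once, with the summit and signal of its strongest line, which reduced the 8536 lines of the main set to 7819 peaks. Analyses used chromosome arms 2L, 2R, 3L, 3R, 4 and X, which held 7804 of them. Coordinates are those of dm6, counted from 1. The annotation was Ensembl release 115 of the BDGP release 6 assembly, which has the same coordinates, and each peak ended inside its arm. Transposable elements were left out, leaving 18164 genes, 13945 of them protein-coding, and 23998 transcription start sites (TSSs).

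A summit within 500 bp of a TSS was called a promoter summit, and a gene with such a summit was called promoter-bound. Other summits were assigned, in this order, to 5' UTR, 3' UTR, coding exon, noncoding exon, intron or intergenic sequence. Shares of summits were tested by a permutation test in which the summits of an arm were shifted together around that arm 100000 times. That test was one-sided for overlaps between peak sets and two-sided for location classes. The smallest p it can give is 1e-05 one-sided and 2e-05 two-sided. Promoter-bound genes of 24 gene lists were compared with all other genes, and genes on X with those on 2L, 2R, 3L and 3R, by two-sided Fisher's exact tests. Of 28 known sequence motifs, the share of peaks with a match within 50 bp of the summit was compared with a window of equal length 250 bp to one side by two-sided exact McNemar tests. Words of 8 bases were ranked by the same contrast on arms 2L, 2R and 4, and the top 10 were tested on 3L, 3R and X. The median signal of promoter and distal peaks was compared by a two-sided permutation test with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each family, and 0.05 was the threshold. Values per replicate were computed from each replicate's own thresholded list and are given as mean ± SD (n = 3). Confidence intervals of shares are 95% Wilson intervals and cover counting error only. Peaks and genes of 1 list are not independent replicates, so these p-values describe the peak set and not variation between embryos.

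Genes were named by a rule. It took the 20 strongest main peaks whose summit lay in a thresholded peak of all 3 replicates, named by the nearest TSS, the 5 strongest of these over 500 bp from any TSS, up to 4 bound members of each gene list by strongest promoter peak, and CG17361. Other names were chosen after their values were seen. The design, gene lists, motifs and this rule were fixed before the data were examined. Of the symbols in the lists, 3 were not found in the annotation (Z4, poils and nos) and 4 were matched through a synonym. Alternatives planned in advance were the pooled set, an IDR of 0.01, the strongest peaks by signal, peaks found in all 3 replicates, each pair of replicates, TSS windows of 250 and 1000 bp, other overlap rules, other backgrounds for the gene lists, and other windows and controls for the motifs. Alternatives chosen after seeing the data were an IDR of 0.001, every deposited line, merged overlapping intervals, the ranked peaks that the thresholded list lacks, shifts of 10 to 100 kb, and control windows matched on arm, location class and GC content. These control windows were centred outside all peaks of the main ranked list and were not matched on distance to a TSS.

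Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The tests were tried on simulated data. The shift test called 1 of 20 sets of random summits, and all 20 sets in which 200 of 2000 summits had been placed at a TSS. The list test made no call among 24 lists in 20 sets of randomly bound genes, and called the mitochondrial ribosomal protein genes in 20 of 20 sets with 60% of them bound. Genes were bound independently in these sets, whereas neighbouring genes can share a peak in the data, so false calls through sharing were not measured. A word planted in 5% of 4000 windows was ranked first and passed the test on the other arms in 5 of 5 sets. The signal test called 0 of 20 sets with no difference and 20 of 20 with a signal 1.2 times higher.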

Results

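The data are peak lists from ChIP-seq of GFP-tagged CG17361 protein in whole Drosophila embryos aged 0 to 24 hours, in 3 biological replicates of 1 group. The lists give the genomic positions at which the tagged protein was recovered above a control library. The replicates' own thresholded lists held 5942, 3797 and 5576 peaks on the 6 chromosome arms for replicates 1, 2 and 3, or 5105 ± 1147 (SD, n = 3), and the largest was 1.56 times the smallest. The lists that compare a pair of replicates by IDR held 5319 peaks for replicates 1 and 2, 7804 for replicates 1 and 3, and 4157 for replicates 2 and 3. The pooled list held 8143 peaks. The list of replicates 1 and 3, which the authors named conservative, is the main set described below.

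Peaks of the replicates lay at the same places far more often than shifted positions did. Of the summits of replicate 2, which has the shortest list, 82.9% lay in a peak of replicate 1 and 82.8% in a peak of replicate 3. In turn, 55.5% of the summits of replicate 1 and 57.2% of those of replicate 3 lay in a peak of replicate 2. Of the summits of replicates 1 and 3, 76.5% and 77.4% lay in a peak of the other. Shifted summits gave between 1.01% and 2.15% (one-sided permutation test of shifts, p = 1e-05 for each, the smallest it can give). Of the main peaks, 2878 (36.9%) had their summit in a thresholded peak of every replicate, against 0.656% of shifted summits. The main list was made from all 3 replicates' alignments and filtered by IDR between replicates 1 and 3. An overlap with the replicates above that of shifted summits therefore follows from its construction. A further 1946 main summits lay in peaks of 2 replicates, 1501 in peaks of 1, and 1479 in none. The median signal score rose with this number, from 133.1 for peaks found in no replicate's own list to 377.3 for peaks found in all 3. Across peaks of the ranked lists, the signals of both replicates correlated with a Spearman rho of 0.637 for replicates 1 and 2, 0.640 for replicates 1 and 3, and 0.598 for replicates 2 and 3. Peaks are not independent replicates, and these values describe the lists. The share found in every replicate depended on the peaks considered and was 68.8% in the 3902 peaks of the main set with the highest signals.

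The tagged protein was found mainly at promoters and in introns, and almost never in coding sequence. Promoter summits, within 500 bp of a TSS, made up 46.2% of the main set (3603 of 7804 peaks), 3.41 times the 13.5% of shifted summits. In the replicates' own lists the share was 50.1% ± 1.69 (SD, n = 3). Introns held 34.6% of the summits and intergenic sequence 16.9%, both below the shifted shares of 39.4% and 27.4%. Coding exons outside promoters held 20 summits, or 0.256%, where shifting gave 13.1%. The 3' UTRs held 0.833%, where shifting gave 5.06%, and the 5' UTRs 0.384%, where shifting gave 0.779%. Each of these 6 classes passed the threshold (two-sided permutation test of shifts, adjusted p = 2.33e-05, from the smallest p it can give), and noncoding exons, with 0.871% against 0.817%, did not (adjusted p = 0.679). Each class share differed between the replicates by less than its distance from the shifted share, apart from noncoding exons. The shortfall in introns was not past the threshold when promoters were limited to 250 bp (39.7%, adjusted permutation p = 0.158, the highest of its 14 alternatives). That in 5' UTRs was not past it among peaks found in all 3 replicates (0.452% against 0.781%, adjusted permutation p = 0.0608).

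**Figure D1:**
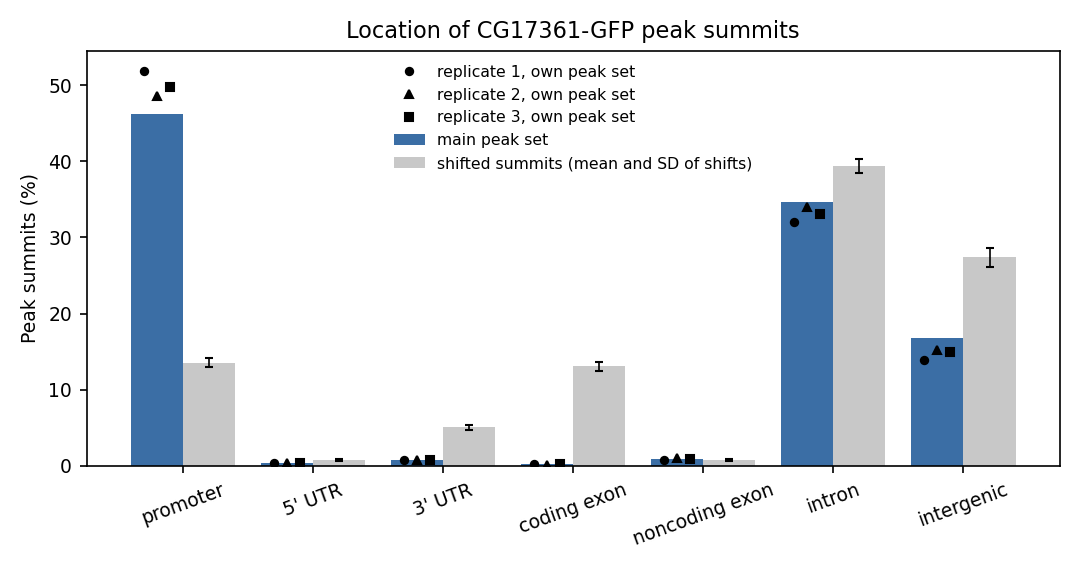
Share of peak summits (y axis, %) in each location class (x axis) for the main peak set (blue bars), for circularly shifted summits (grey bars, with error bars for the SD over shifts) and for each replicate's own list (points). Promoters held 46.2% of main summits against 13.5% after shifting, and coding exons held 0.256% against 13.1%.

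Promoter peaks were also the stronger ones. Their median signal score was 225.6, against 206.5 for the 4201 distal peaks, a difference of 19.1 (two-sided permutation test, p = 1e-05, the smallest it can give). The difference had the same direction in each replicate's own list. Among the 500 strongest main peaks, 66.8% were promoter peaks and 98.2% were found in all 3 replicates. The median distance from a promoter summit to the nearest TSS was 146 bp.

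The strongest peak of the main set lay at CG14100, on 3L from 19590316 to 19590903, with a signal of 1310 and its summit 92 bp from the TSS. It ranked 2, 2 and 1 in the lists of replicates 1, 2 and 3. Of the 20 strongest peaks found in all replicates, 13 were promoter peaks, 5 lay in introns, 1 in a noncoding exon and 1 in intergenic sequence. Several promoter peaks lay near TSSs of more than 1 gene. The peak at 3R 15229257 to 15229820 (signal 1182) was within 500 bp of TSSs of Art3 and of mRpS10, which encodes a protein of the mitochondrial ribosome. Those at Hrd3 and PTPMT1 (1176), at CG1602 and PIG-G (1163), at Pal1 and Pdrg1 (1125), at mRpL41 and lncRNA:CR44463 (1112), and at CG5611 and Mtl (1110) were likewise shared. The remaining promoter peaks of this group were at cu (1154), px (1143), CG3961 (1104), Ugalt (1102), CG31145 (1093) and gish (1084).

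The strongest distal peak lay inside an intron of Trl, the gene of the GAGA factor, which binds GA-rich promoters and enhancers. It spanned 3L 14759206 to 14759891 with a signal of 1188 and a summit 1520 bp from the nearest TSS, and it was the strongest peak of replicate 2. The next were an intronic peak of CG32772 on X (1162, 1272 bp from the TSS) and an intergenic peak on 2R nearest to CG13321 (1160, 4692 bp from the TSS). A peak on X, from 7306851 to 7307577, lay in intron sequence of CG1677 and lncRNA:CR44357 (1136). The nearest TSS, 697 bp away, was that of brk, which encodes a repressor of Dpp target genes. The fifth, in an exon of lncRNA:Vinr, was nearest to lncRNA:CR44619 (1134). Intronic peaks at CG11050 (1119) and in Dif near lncRNA:CR44409 (1103) completed the 20.

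Of 18164 annotated genes, 4055 (22.3%) were promoter-bound, including 26.4% of protein-coding genes and 9.38% of genes for noncoding RNAs of the annotation's general class. The replicates' own lists gave 3511, 2442 and 3333 bound genes. Of the 24 gene lists, 7 held more bound genes than the rest of the annotation and 6 held fewer.

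Genes for the cytosolic ribosome had the highest share of all 24 lists. Of 92 such genes, 74 (80.4%, 95% interval 71.2 to 87.3) were bound, against 22.03% of other genes (two-sided Fisher's exact test, log2 odds ratio 3.83, adjusted p = 6.59e-31), and in the replicates' own lists the share was 65.9% ± 9.50 (SD, n = 3). Promoter peaks of this list included those at RpS27 (signal 889), RpL32 (651) and RpL28 (650.3). Genes for the mitochondrial ribosome followed the same direction with 38 of 73 bound (52.1%, log2 odds ratio 1.93, adjusted exact p = 1.24e-07), led by mRpS10, mRpL41, mRpS23 (897) and mRpL23 (889). Translation initiation factors were bound at 17 of 44 genes, among them eIF6 (656), eIF1 (650.3, a peak shared with RpL28), eIF3c (552) and eIF3m (412), with a log2 odds ratio of 1.15 and adjusted exact p = 0.0333. This call was lost against protein-coding genes alone (adjusted exact p = 0.149) and in both settings that left out replicate 1 or 3, with log2 odds ratios of 0.11 and -0.15. Over its 15 alternatives the adjusted exact p ranged from 0.000711 to 1. The main list lacks promoter peaks at eIF4EHP, eIF4A and RpL13A that stood in the ranked list past an IDR of 0.01, and these genes were counted as unbound. The lists for respiration, protein breakdown and cell division did not pass in the main set. They were 26 of 80 subunits of oxidative phosphorylation complexes (adjusted exact p = 0.0596), including ND-MWFE, ND-42, ND-ASHI and ND-23, 17 of 48 proteasome subunits (adjusted exact p = 0.0596), including Rpn5, Prosbeta2, Rpn11 and Rpn3, and 11 of 28 genes of DNA replication and the cell cycle (adjusted exact p = 0.0596), including Mcm2, Cdk1, aurA and dup. Under 4, 2 and 2 of their 15 alternatives they passed, with adjusted exact p from 0.000726 to 1, from 0.00212 to 1 and from 0.00500 to 0.704.

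**Figure D2:**
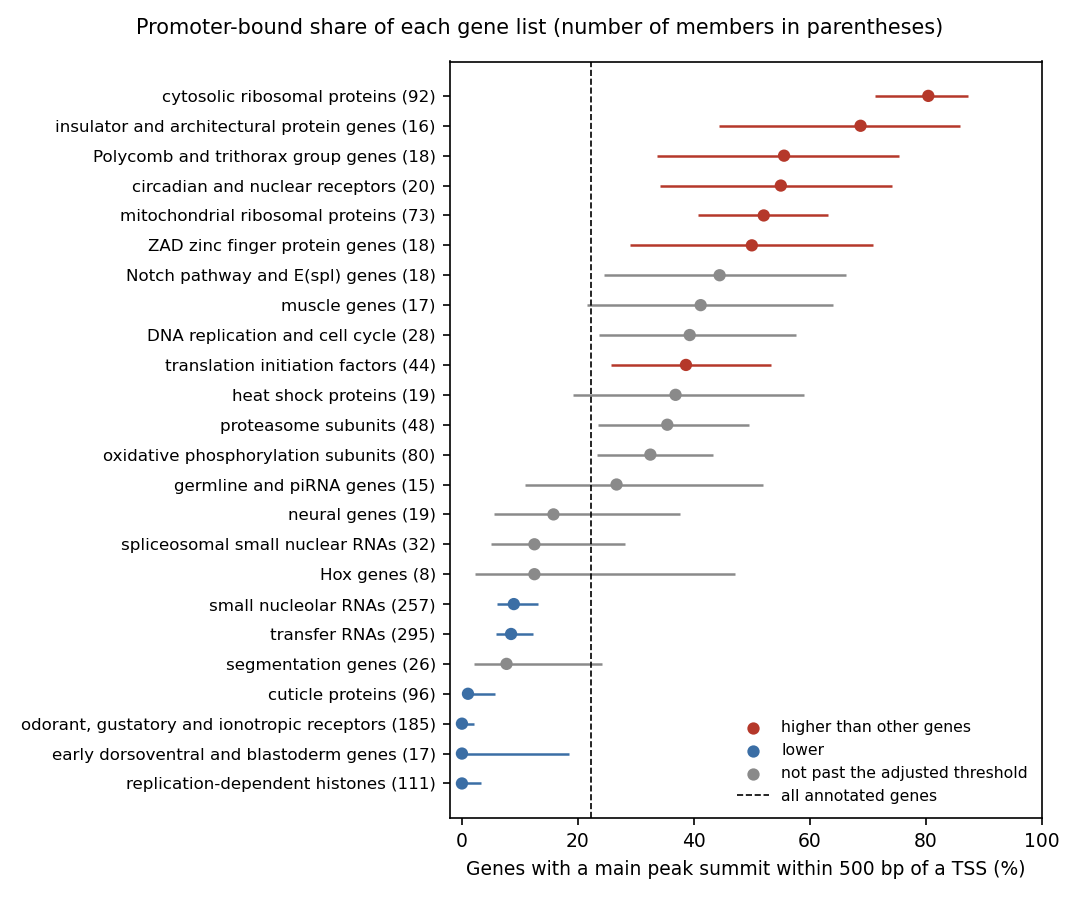
Share of each gene list with a main summit within 500 bp of a TSS (x axis, %), with 95% Wilson intervals (lines) and the number of members in parentheses. Red lists were higher and blue lists lower than other genes past the adjusted threshold, grey lists were not past it, and the dashed line marks all annotated genes (22.3%). Cytosolic ribosomal protein genes (80.4%) lie at the top, and histone and chemoreceptor genes (0%) at the bottom.

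Genes that encode chromatin and insulator proteins were bound often. Of 16 genes for insulator and architectural proteins, 11 were bound (68.8%, 95% interval 44.4 to 85.8, log2 odds ratio 2.87, adjusted exact p = 0.000285), and 66.7% ± 9.55 (SD, n = 3) were bound in the replicates' own lists. The strongest were Chro (signal 1069), Cp190 (902), M1BP (836) and Dref (488), and BEAF-32, CTCF, su(Hw), Trl, Clamp, pita and pzg were bound too. Of 18 Polycomb and trithorax group genes, which keep homeotic genes silent or active, 10 were bound (55.6%, log2 odds ratio 2.11, adjusted exact p = 0.00532), led by brm (900.2), E(z) (797), pho (620.3) and Su(z)12 (398). This call was not past the threshold among peaks found in all 3 replicates (adjusted exact p = 0.179, with 0.000397 to 0.179 over all alternatives). Of 18 zinc finger genes of the ZAD family chosen for the list, 9 were bound (50%, log2 odds ratio 1.80, adjusted exact p = 0.0198), led by M1BP, trem (621), D19B (509) and D19A (319). This list was picked by name, so its share is not that of the whole family. CG17361, the tagged gene, is itself 1 of the 9. Some genes stand in more than 1 of these lists, such as M1BP and pita. The ZAD call was lost against protein-coding genes alone (adjusted exact p = 0.0602, with 0.00181 to 0.0758 over all alternatives). The list of circadian and nuclear receptor genes had 11 of 20 members bound (55%, log2 odds ratio 2.08, adjusted exact p = 0.00396), led by Hnf4 (766), Eip75B (604), ERR (535) and Hr78 (468). Its members have many TSSs, and 1473 of 10000 random lists matched on gene type and number of TSSs had as many bound, so this share was not beyond that of such genes. The call was lost without replicate 3 (log2 odds ratio 1.58, adjusted exact p = 0.0514, the highest of its 15 alternatives). Of matched random lists, 8 in 10000 reached the share of the insulator genes, 244 that of the Polycomb and trithorax genes, 80 that of the ZAD genes, 579 that of the initiation factors, and none that of either ribosomal list.

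Genes for chemoreceptors and cuticle proteins were rarely bound. None of 185 odorant, gustatory and ionotropic receptor genes was bound, which allows a share of up to 2.03% (adjusted exact p = 9.71e-20), and 1 of 96 cuticle protein genes was, TwdlU (adjusted exact p = 6.91e-09). Of 17 early dorsoventral and blastoderm genes none was bound (adjusted exact p = 0.0356). That call was lost under 10 of 15 alternatives (adjusted exact p from 0.0268 to 0.340), and 1 member was bound in the list of replicate 1 (5.88%). The TSS of brk, also a member, was the nearest to the strong peak described above, but outside the 500 bp limit. Segmentation genes had 2 of 26 members bound, bcd (260) and ptc (154), and Hox genes 1 of 8, Antp (291), with adjusted exact p of 0.121 and 0.756, so neither differed past the threshold. The segmentation list passed as lower at an IDR of 0.001 (log2 odds ratio -3.35, adjusted exact p = 0.0292, with up to 0.374 over its 15 alternatives), and 142 of 10000 matched random lists had as few bound. The 3 bound neural genes of 19 were elav (786), nerfin-1 (302) and scrt (185), with adjusted exact p = 0.782. Muscle genes had 7 of 17 bound, including Tm1 (619), tin (505), Act87E (502) and sls (422), with adjusted exact p = 0.103 and a range of 0.0187 to 0.558 over the alternatives, of which 1 passed. Of the genes of the Notch pathway and the E(spl) complex, 8 of 18 were bound (adjusted exact p = 0.0596), including E(spl)m3-HLH (1082), E(spl)m7-HLH (806), E(spl)m2-BFM (698) and neur (610). The heat shock list had 7 of 19 bound (adjusted exact p = 0.196), including Hsp27 (868), Hsc70-5 (774), Hsc70-4 (520) and Hsp26 (396). Among peaks found in all 3 replicates, the Notch list (adjusted exact p = 0.0174) and the heat shock list (adjusted exact p = 0.00588) passed the threshold. Over all alternatives the adjusted exact p ranged from 0.00709 to 0.755 for the Notch list and from 0.00588 to 0.354 for the heat shock list. Germline genes had 4 of 15 bound, spn-E, bgcn, armi and squ (adjusted exact p = 0.782).

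Transfer RNA and small nucleolar RNA genes were bound less often than all other genes, at shares near the 9.38% of general noncoding genes, a difference that was not tested. The share was 25 of 295 for transfer RNA genes (8.47%, adjusted exact p = 1.89e-09), with the strongest peaks at tRNA:Tyr-GTA-1-8 (554), tRNA:Val-CAC-2-5 (339), tRNA:Trp-CCA-2-2 (321) and tRNA:Leu-TAA-2-1 (265). It was 23 of 257 for small nucleolar RNA genes (8.95%, adjusted exact p = 6.59e-08), with the strongest at snoRNA:Psi28S-2949 (556), snoRNA:Psi18S-920 (417), snoRNA:Or-aca2 (378) and snoRNA:Or-ACA6 (347). With a TSS limit of 1000 bp the small nucleolar RNA genes no longer differed past the threshold (adjusted exact p = 0.831, the highest of its 14 alternatives). Of 32 spliceosomal small nuclear RNA genes, 4 were bound (adjusted exact p = 0.239, with 0.0140 to 0.720 over its 14 alternatives, 3 of which called the list lower), snRNA:U5:63BC, snRNA:U6:96Ab, snRNA:U6:96Ac and snRNA:U1:95Ca. None of 111 replication-dependent histone genes was bound, which allows a share of up to 3.35% (adjusted exact p = 7.34e-12). Histone, transfer RNA and small nuclear RNA genes occur in near-identical copies, where reads cannot be placed uniquely, so a low share at these genes is uncertain. In each of the 13 lists past the threshold the direction was the same in 3 of 3 replicates. For initiation factors in replicate 2 the shares were nearly equal, at 13.6% against 13.4% of other genes. The main set was made from the same replicates, so this agreement is not independent of it.

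Genes on X were bound slightly more often in the main set, and this did not hold in the replicates. Of 2813 genes on X, 683 (24.3%) were bound, against 3348 of 15233 (21.98%) on 2L, 2R, 3L and 3R (two-sided Fisher's exact test, odds ratio 1.14, p = 0.00779). In the replicates' own lists the odds ratios were 1.02, 0.950 and 1.02, with exact p of 0.735, 0.400 and 0.750, and with a TSS limit of 250 bp the odds ratio was 1.01. On chromosome 4, 24 of 118 genes were bound.

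The summits lay in AT-rich sequence. Within 50 bp of the summit the mean GC content was 32.4%, against 42.8% in windows 250 bp to each side, and in the replicates' own lists it was 31.6% ± 0.937 against 43.1% ± 0.708 (SD, n = 3). The dip was present at promoter, intron and intergenic peaks, with 33.1%, 31.7% and 31.3% GC, and was deeper at the 500 strongest peaks, with 26.5% against 45.2% in their flanks. This measurement was added after the 8-base words had been seen. All 10 words of 8 bases that led on arms 2L, 2R and 4 passed on 3L, 3R and X, and all 10 consisted of A and T. ATATTTTA stood in 6.23% of the tested centres and 1.79% of their flanks (exact McNemar test, adjusted p = 1.57e-29), and TTTAAAAA in 7.24% and 2.46%.

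**Figure D3:**
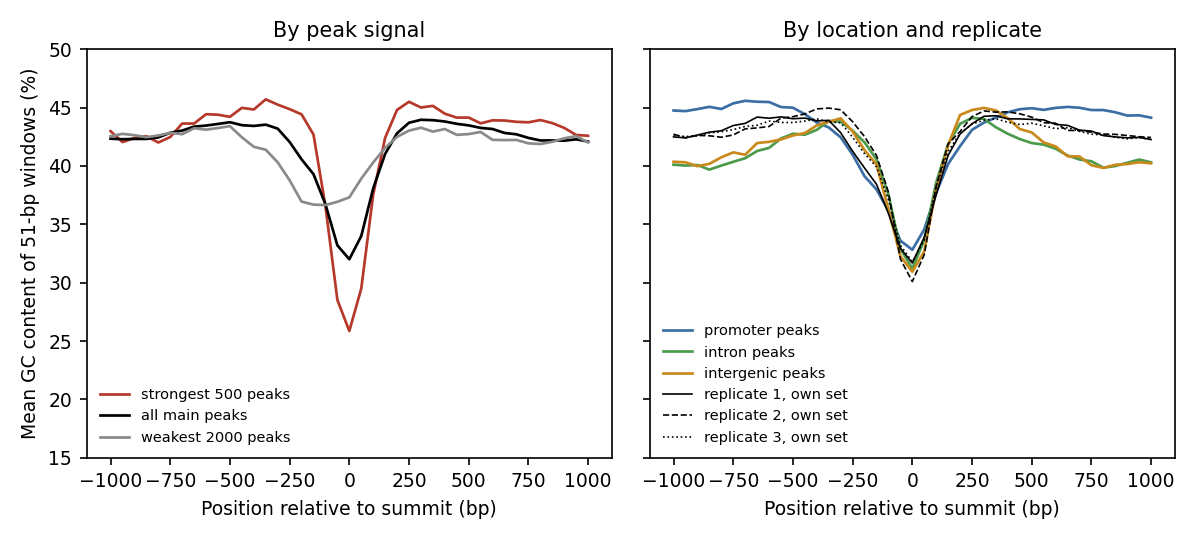
Mean GC content of 51-bp windows (y axis, %) by position relative to the summit (x axis, bp), for main peaks by signal (left) and for main peaks by location and each replicate's own list (right). The lines dip at the summit, to 25.9% for the 500 strongest peaks and 32.0% for all main peaks, and the line of the 2000 weakest peaks has a shallow minimum of 36.7% on the low-coordinate side.

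Of the 28 known motifs, 9 were more frequent at summits than in the flanks and 12 less frequent. The TATA box stood at 10.5% of centres and 4.15% of flanks, the homeodomain core TAATTA at 11.3% and 5.30%, GATA sites at 22.5% and 16.7%, and runs of 8 A at 8.10% and 5.66% (exact McNemar tests, largest adjusted p of these 9.14e-09). The others called higher were the DREF element, with 1.81% and 0.987%, the BEAF-32 site, the E-box CATATG, the Su(Hw) site and the Bicoid site. GAGA factor sites were less frequent at centres, with 8.35% against 15.1%, as were CA repeats, Pleiohomeotic, Runt, Zelda, Ewg, CTCF and initiator sites, GA repeats, the polypyrimidine element and the E-boxes CACGTG and CAGCTG. The heat shock element, Dorsal, AP-1, Hunchback, M1BP, Ohler 7 and tRNA B box motifs were not past the threshold. Of the calls made, those for the Bicoid, Zelda and Ewg sites were kept under 10, 9 and 8 of 16 alternatives. These contrasts moved with the control windows. The windows matched on GC content were centred outside all peaks of the main ranked list, so they differ from summits in more than position. Against windows matched on GC content, the TATA box (10.4% and 10.6%, adjusted exact p = 0.821), the homeodomain core (11.3% and 12.2%, adjusted exact p = 0.153) and GATA sites (22.5% and 21.7%, adjusted exact p = 0.383) did not differ past the threshold, and runs of A were less frequent at summits (8.10% and 10.4%, adjusted exact p = 2.56e-06). The DREF element (1.81% and 0.423%, adjusted exact p = 7.27e-16) and the BEAF-32 site (12.5% and 9.71%, adjusted exact p = 1.78e-07) were more frequent in both contrasts in the main set. The contrast of the DREF element with flanks was lost without replicate 1 (log2 ratio 0.27), without replicate 3 (0.28), in the strongest peaks (0.40) and in peaks found in all 3 replicates (0.27), where the main set gave 0.87. That of the BEAF-32 site, 0.18 in the main set, was lost under 6 of 16 alternatives, among them peaks found in all 3 replicates (0.064), an IDR of 0.001 (0.094), the strongest peaks (0.13), merged intervals (0.14) and without replicate 1 (-0.038). Against matched windows the direction turned for the CTCF core (2.96% and 1.56%, adjusted exact p = 9.18e-09) and CAGCTG (3.05% and 2.14%, adjusted exact p = 0.00155), both more frequent at summits. M1BP (0.743% and 0.205%, adjusted exact p = 3.87e-06) and Ohler 7 motifs (3.998% and 2.27%, adjusted exact p = 5.64e-09) were more frequent there too. None of the 12 motifs less frequent than in flanks was less frequent than in matched windows past the threshold. GAGA factor sites stood at 8.36% of centres and 7.38% of matched windows (adjusted exact p = 0.0674). At promoter peaks neither the DREF element nor the BEAF-32 site differed past the threshold from TSSs of unbound genes (3.36% and 3.10%, adjusted exact p = 0.474, for the DREF element). Windows of promoter peaks were centred on summits, at a median of 146 bp from the nearest TSS. Those of unbound genes were centred on the most upstream TSS. The contrast therefore mixes position with binding and does not show whether bound promoters differ from unbound ones.

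The locus of CG17361 itself, FBgn0036395 on the plus strand of 3L from 13997191 to 13998055, carried a promoter peak. It spanned 13996765 to 13997374 with a signal of 238.7, rank 3336 of 7804, and its summit lay 121 bp from the TSS. Peaks at this promoter stood in the lists of replicates 1 and 3, and none in that of replicate 2. Of the 7 main peaks within 10 kb of the gene, the strongest, with a signal of 660.4 and rank 372, lay 2942 bp from the TSS of upSET and was found in all 3 replicates.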

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

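The excluded regions and the repeated sequence described here were predicted before their tests were run, and the counts of missing peaks by arm and by gene were chosen after the result was seen.

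The main list held 15 peaks on the mitochondrial genome, which no comparison of the report uses, and the strongest had a signal of 929.9. They came to attention as signal in data that were left aside, with no control library analysed here to set a background. No explanation was tested for them.

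A second set that came to attention was 149 peaks with an IDR of 0.01 or less in the ranked list of replicates 1 and 3 that the thresholded list of the same pair lacks, or 1.87% of the peaks past that limit. They were not weak, with a median signal of 232.1 against 213.7 for the peaks kept, and 102 of them (68.5%) lay on 3R. The strongest, at 3R 24108865 to 24109486 with a signal of 1189, lay at the promoters of CG18428 and eIF4EHP and ranked 2 when added to the main peaks. Others lay near Kdm2 (1019), Lk6 (967.4), cbt (956.7), Alh (933.8) and pont (848.1), and at promoters of RpL13A, E2f1 and Hr39, which the report counts as unbound. These genes were named after their values were seen.

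Of the summits of these missing peaks, 3.36% lay in a peak of any thresholded list, so nearly all of them were absent from every such list. This is what a list of regions excluded by the authors would give, and such a list is a candidate explanation. Repeated sequence as the reason is argued against, since soft-masked bases were 0.854 times as frequent in the missing peaks as in the kept ones. Why such regions would gather on 3R stays open. The design has 1 group, and no biological explanation was tested.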

How the results depend on the processing

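An IDR of 0.001, every deposited line, merged intervals, the added ranked peaks, shifts of 10 to 100 kb and windows matched on GC content were chosen after the data had been seen, and the other alternatives before. The promoter share of summits kept its direction and side of the threshold in 16 of 16 alternatives (34.4% to 55.8%), and the signal difference of promoter and distal peaks in 13 of 13 (12.7 to 64.2). Each alternative for the words ranked its own set, of which 10 of 10 passed with 6 bases or with arms exchanged and 9 of 10 against windows matched on GC content. The share of peaks found in every replicate ranged from 21.6% to 68.8%, the highest in the strongest peaks. With a replicate left out, only the remaining replicates were required, and the share was 55.4% to 72.8%. An IDR of 0.01 removed no peak, and the set without replicate 2 is the main set itself, so these settings test nothing except, for the latter, the share found in the remaining replicates. A replicate left out was dropped from the IDR comparison alone, since the peaks were made from all replicates' alignments. Leaving out assembly gaps removed no summit and changed only the shifted share, to 13.6%.

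Where results changed, the cause was not tested unless stated. The 5' UTR share was no longer past the threshold among peaks found in all 3 replicates (0.452%), where fewer peaks were tested, nor the intron share with a TSS limit of 250 bp (39.7%). The odds ratio for X reversed in the strongest peaks (0.969) and in peaks found in all 3 replicates (0.968), was not past the threshold at an IDR of 0.001 (1.02) or a TSS limit of 250 bp (1.01), and ranged from 1.03 to 1.14 when each replicate was left out, lost without replicate 1 and without replicate 3. An IDR of 0.001 kept 4573 peaks, by construction. Spearman's rho over peaks past the threshold alone was 0.511 for replicates 1 and 2 and 0.741 for replicates 1 and 3. Counting genes that share a promoter peak once raised the lists called higher to 13, since only bound genes are merged and the bound share of other genes falls. Of 13 gene lists past the threshold, 7 kept their call in every alternative run: both ribosomal lists, the insulator genes, transfer RNAs, histones, chemoreceptors and cuticle proteins. The log2 odds ratio of the initiation factors ranged from -0.15 to 1.15 when each replicate was left out, and reversed without replicate 3.

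Of 21 motifs past the threshold, 0 kept their call in every alternative. Against windows matched on GC content 2 motifs were lower, the A tract and Hunchback, and neither was lower against flanks. These windows differ from flanks in position and composition and were centred outside ranked peaks, so the cause of the change was not separated. Against them the log2 ratio reversed for the GAGA factor (0.18), GA repeat (0.59), CACGTG (0.29), CAGCTG (0.51), TATA box (-0.019), CTCF core (0.92), Bicoid (-0.24), homeodomain (-0.11), A tract (-0.36), Runt (0.21), Hunchback (-0.55) and Ohler 7 (0.82). At the TSSs of unbound genes, with windows centred on a TSS and not a summit, it reversed for the GA repeat (0.34), M1BP (-0.72) and TCT (0.41). It also reversed with flanks at 500 bp for Ohler 7 (0.45), in the strongest peaks for M1BP (-1.42), and without replicate 1 for M1BP and BEAF-32. The ranges of M1BP and BEAF-32 when each replicate was left out were -1.15 to 0.13 and -0.038 to 0.21.

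Lists, motifs and a location class past the threshold neither in the main set nor in the alternative also changed direction. The noncoding exon share fell below the shifted share in the strongest peaks (0.794%), at an IDR of 0.001 (0.765%) and with a TSS limit of 1000 bp (0.474%). The log2 odds ratio changed sign for Hox genes in the strongest peaks (0.26), at an IDR of 0.001 (0.062) and with shared peaks counted once (0.032), where neural genes did too (0.12). It did so for proteasome subunits in peaks found in all 3 replicates (-0.21), for the Notch list with a TSS limit of 250 bp (-0.42), and for germline genes at an IDR of 0.001 (-0.049) and with merged intervals (-0.0024). With each replicate left out it ranged from -0.52 to 0.35 for Hox genes, -0.44 to 0.18 for neural genes and -0.048 to 0.95 for proteasome subunits. The log2 ratio changed sign for M1BP in peaks found in all 3 replicates (-0.89), at an IDR of 0.001 (-0.72) and with merged intervals (-0.14), and for the heat shock element in the pooled set (-0.34), in peaks found in all 3 replicates (-0.36) and with flanks at 500 bp (-0.87). It did so for the tRNA B box with every deposited line (-0.39), merged intervals (-0.53) and the added ranked peaks (-0.24), and was 0 at an IDR of 0.001 and in windows of 25 bp. For Ohler 7 it was 0.077 in the pooled set, 0.12 with every deposited line, 0.073 with the added ranked peaks and 0.10 in windows of 100 bp. AP-1 reached 0.055 in windows of 25 bp and 0.37 against windows matched on GC content, Dorsal 0.20 against the latter and 0.18 at TSSs of unbound genes, and Hunchback 0 in the strongest peaks. With each replicate left out the ratio ranged from -0.89 to 1.28 for the heat shock element, -0.29 to 0.29 for the tRNA B box and -0.036 to 0.11 for Hunchback.

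The depth of the libraries is unknown, so what it limits could not be measured.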

Other observations

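The tests on base composition of promoters, on AT-rich stretches in GC-richer surroundings and on oxidative phosphorylation genes were chosen after the result was seen, as were the counts of overlapping peaks and of summits per gene, and the others were written before it.

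The low GC content at summits was weighed against technical explanations. Recovery of AT-rich DNA wherever it lies is argued against as the whole cause, since 16.8% of equally AT-rich windows lay in ranked peaks, which cover 14.6% of the arms. Ranked peaks include those that do not pass the IDR, and 3.89% of these windows lay in the thresholded main peaks. A partial bias towards AT-rich DNA stays open, because it need not reach the bound set for the test. Recovery of AT-rich stretches set in GC-richer DNA stays open. Of such windows, 21.5% lay in ranked peaks, between the bounds set for the test. Whether they resemble the summits more closely than the other AT-rich windows do was not measured. The composition of promoters is argued against too, since summits over 500 bp from any TSS had a mean GC difference of -11.8 percentage points from their flanks. Open chromatin that is AT-rich whichever protein is bound stays open. The most AT-rich window near the TSS was 2.81 points richer in GC at unbound than at bound genes, short of the 5 points that would have argued against it. At unbound genes that window held 23.2% GC, not within 2 points of the 33.1% at promoter summits but below it, and at bound genes 20.4%. The lowest of many windows tends to lie below a window fixed at the summit. The comparison therefore shows only that unbound promoters hold AT-rich stretches too, and not that these resemble the summits. No accessibility data were used here.

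The high share of cytosolic ribosomal protein genes was weighed likewise. A larger target through more TSSs per gene is argued against, since the highest share among 10000 matched random lists was 47.8%. Recovery of strongly transcribed promoters in any immunoprecipitation cannot be told apart from binding by CG17361, since the values of the authors' control library were not analysed here. Oxidative phosphorylation genes were bound at 32.5%, between the bounds set for the test. This list was picked by gene symbol and includes paralogues such as COX4L. The ribosomal list was bound more often than that list (odds ratio 8.28, exact p = 2.33e-10). How widely and how strongly the genes of both lists are transcribed was not compared, so this difference does not decide the question. No biological explanation was tested for either pattern, because the design has 1 group.

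Against windows matched on GC content and centred outside ranked peaks, 9 of the 10 leading words of 8 bases passed on the held-out arms. They were not those seen against flanks. The following shares are over all arms, so they include the peaks from which the words were picked. At promoter peaks TATCGATA, the DREF element, stood in 3.36% of centres and 0.555% of matched windows. Among the 2000 strongest peaks it stood in 0.75% and 0.45% (exact p = 0.307), and among the others in 2.17% and 0.448%. At distal peaks GGGCGCCA stood in 1.19% and 0.0476%, CACTGAGA in 1.5% and 0.167%, and AGATGGCG in 0.857% and 0.0476%. A hypothesis was that TATCGATA is carried by promoter peaks alone. Its ratio at distal peaks was 1.54 (exact p = 0.296), between the bounds set for the test, so this stays open.

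Of the main peaks, 1232 (15.8%) overlapped a stronger main peak, and the summit lay at the higher coordinate in 1183 of them (96.0%), at a median distance of 204 bp. Their centres had 39.9% GC, against 31.0% for the other peaks. They made up 42.05% of the 2000 weakest peaks, and the 1159 of these free of such overlap had a GC difference of -7.70 points from their flanks.

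The genes with the most main summits were kirre with 36, lncRNA:CR44357 with 27, CG1677 with 22, fz with 20, Eip75B with 19 and shn with 19. CG1677 lies inside lncRNA:CR44357, so its 22 summits are among the 27. Per 10 kb this was 0.913 for kirre, 2.12 for fz and 3.26 for shn, where the genome had 0.583. The genes were picked by their counts in this list, so rates above that of the genome follow in part from the choice. They were not tested.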
